A study of Homo sapiens with 14 samples.

How the data were processed

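The series comprised 14 libraries from HepG2 cells: 10 DNA libraries for mapping 6mA on mitochondrial DNA by CLIP-exo, in which crosslinked antibody protects a site from exonuclease, and 4 RNA libraries for a METTL4 knockdown. Groups were read from the library titles: Input, NEB and SYSY in hypoxia or normoxia, and siMETTL4 or siCtrl. The labels do not say how NEB and SYSY differ, how low the oxygen was or how long cells were exposed to it, and the DNA libraries carry a conflicting molecule label of total RNA beside the characteristic mtDNA.

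The peak lists were deposited by the authors as 3 columns without a header, holding a chromosome, a start and an end, with no height, score, fold or p. Per the submitters' processing notes, the genome build was hg19 and the tools included Bowtie, deepTools and DESeq2, with no role or order given. The peak caller, its threshold, the input set against each immunoprecipitation and the treatment of replicates are not given in the sources used here. The SYSY groups had 2 libraries and 1 list each, so replicates could not be compared and no spread could be computed. Each list was assigned to its label and condition by its own name, which matched the titles of that group alone. In the lists all positions were whole multiples of 10 bases, the shortest peak was 50 bases, and the closest neighbours within a list were 60 to 80 bases apart. A grid and a shortest length of this kind limit the resolution, and wide peaks can merge several sites, so both numbers of peaks and covered bases depend on settings not known here. The hg19 mitochondrial sequence circulates in versions whose numbering differs by a few bases, and the lists do not say which was used. No annotation of that build was used. Gene names beside positions are therefore background for positions well inside a gene or across a stated junction, and no count by gene was made.

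A gene expression table was also deposited, made with HISAT and Cuffnorm on hg19 per the submitters' processing notes. Its 4 value columns carry codes found in no title, description or other label, so they were matched to no library and were not used. The planned fits of siMETTL4 against siCtrl and the 34 gene lists written for them were therefore not run, and METTL4 itself was not examined.

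From the lists were computed the number of peaks, the covered bases, the overlaps between lists and regions joined from all lists. The number of peaks in hypoxia and normoxia was compared with a two-sided exact binomial test, which covers counting error only. Sharing between 2 lists was tested with a one-sided exact circular shift test: 1 list was rotated around the mitochondrial circle in steps of 10 bases, giving 1657 positions with the real one included, and p was the share of positions with at least as many shared bases. Rotation keeps the lengths and the clustering of the peaks. The 4 overlap tests, the named peaks (those in both conditions of a label, those of 1 condition in both labels and the longest of each list) and most alternatives were fixed before the data were examined, with an adjusted p under 0.05 (Benjamini-Hochberg over the 4 tests) as the threshold. The peaks fitting that rule were too many to name singly, so examples are given with the regions common to all lists. The test was tested on simulated lists of the real numbers and lengths, 200 pairs for each comparison. Simulated peaks were placed independently at random, without any clustering. The rates therefore do not cover 2 lists that share a dense stretch. Unrelated lists gave p under 0.05 in 4% of pairs for NEB hypoxia and normoxia, 7.5% for SYSY hypoxia and normoxia, 5.5% for NEB and SYSY in hypoxia and 5% for NEB and SYSY in normoxia. With 50% of the second list copied from the first, all 4 comparisons gave p under 0.05 in 100% of pairs. These copies were exact and kept the lengths of the first list. The result therefore does not apply to peaks that overlap only in part.

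Other settings fixed in advance were counts of overlapping peaks (at least 1 base, or at least 50% of the shorter peak), peaks extended by 50 or 100 bases on each side, and, for the overlap tests alone, lists without their longest peak. Those added after the data were seen were rotation in steps of 1 base, leaving out 1 peak at a time, joining peaks at most 100 or 200 bases apart, covered bases without the longest peak of each list, the tests of stretches without peaks and of peaks far from the other condition, and the overlap of lists that differ in both label and condition. A stricter peak threshold could not be applied, because the lists hold no score. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.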

Results

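Positions of N6-methyldeoxyadenosine (6mA), an adenine carrying a methyl group in DNA, were mapped on the mitochondrial DNA of HepG2 cells, a human liver cancer cell line. Cells were kept under normal oxygen (normoxia) or low oxygen (hypoxia). The 10 DNA libraries comprised 4 inputs, 2 from each condition, and 6 immunoprecipitations. Immunoprecipitations labelled SYSY had 2 libraries in each condition, and those labelled NEB had 1. One peak list stood for each label and condition, giving 4 lists. A further 4 libraries held polyadenylated RNA taken 48 h after transfection with siMETTL4 or siCtrl, with 2 libraries each. METTL4 belongs to a family of adenine methyltransferases. The knockdown comparison was not analysed here, because none of the columns of its gene table could be matched to a library. Sequencing depth was unknown for all libraries, since the lists hold peak positions without read counts or heights.

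The first comparison asked where 6mA peaks lay on the mitochondrial chromosome under each condition. All peaks of the 4 lists lay on chromosome M in hg19 coordinates, given here counted from 1. The NEB lists held 26 peaks in hypoxia and 15 in normoxia. The SYSY lists held 34 peaks in hypoxia and 23 in normoxia. Each list covered a small part of the circle: 1550 bases (9.35%) in NEB hypoxia, 1210 bases (7.30%) in NEB normoxia, 2060 bases (12.4%) in SYSY hypoxia and 2170 bases (13.1%) in SYSY normoxia. Most peaks had the shortest length found, 50 bases. That length applied to 23 of the 26 NEB hypoxia peaks, 11 of the 15 NEB normoxia peaks, 31 of the 34 SYSY hypoxia peaks and 14 of the 23 SYSY normoxia peaks.

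**Figure D1:**
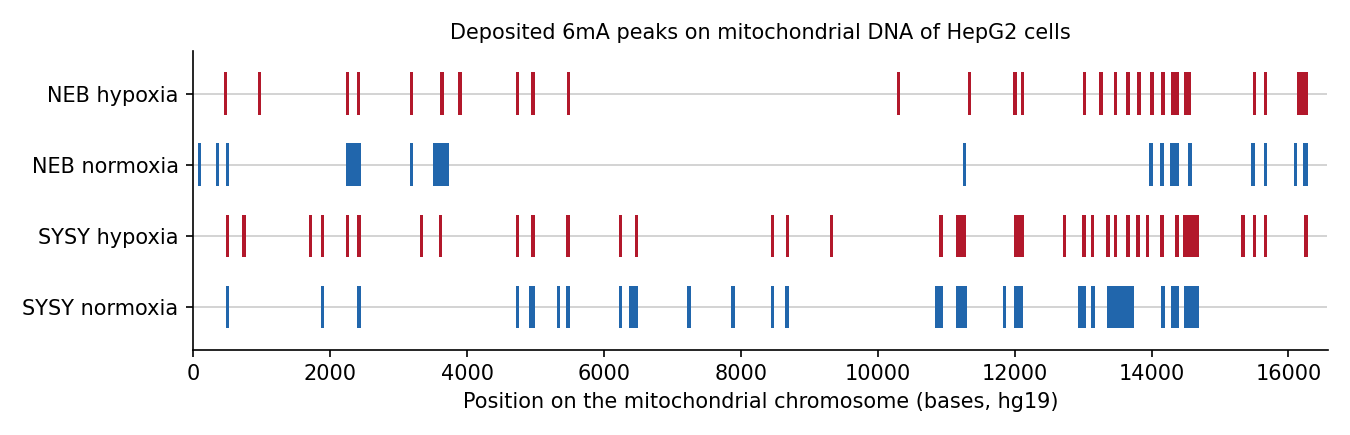
Map of the deposited 6mA peaks along the mitochondrial chromosome (horizontal axis, position in bases, hg19), with 1 row for each label and condition. Each bar is 1 peak drawn to scale, red for hypoxia and blue for normoxia. The NEB hypoxia row has no bar from 5511 to 10280, where both SYSY rows have peaks.

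Peaks that overlapped or touched across the 4 lists were joined into 43 regions. Peaks from all 4 lists fell in 5 of these regions, peaks from 3 lists in 12, from 2 lists in 9 and from 1 list in 17. The 5 regions held by all lists were 451 to 530, 2231 to 2450, 14131 to 14190, 14271 to 14400 and 14461 to 14690. In the standard human mitochondrial gene map, the numbering starts and ends inside the control region, the noncoding stretch that holds the promoters and a replication origin. The region at 451 to 530 lies there on that map. The region at 2231 to 2450 lies in the gene of the large ribosomal RNA, MT-RNR2. The region at 14131 to 14190 spans the junction of MT-ND5 and MT-ND6, and the region at 14271 to 14400 lies in MT-ND6, a subunit gene of respiratory complex I. These gene names are background from the general map. No annotation of the build used for the lists was at hand, so peaks were not counted by gene. Bases covered in every list numbered 190, at 481 to 500, 2401 to 2440, 14141 to 14180, 14351 to 14400 and 14541 to 14580.

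Among windows of 1000 bases, the one from 13001 to 14000 held the most peaks in both hypoxia lists, counted by their midpoints. On the standard map this window lies in MT-ND5. It held 5 NEB peaks in hypoxia and 1 in normoxia. The same stretch held 7 SYSY peaks in hypoxia and 2 in normoxia. One of the 2 SYSY normoxia peaks was the longest of its list, 390 bases from 13351 to 13740. It alone overlapped the SYSY hypoxia peaks at 13341 to 13390, 13451 to 13500 and 13631 to 13680. The other, at 13121 to 13170, overlapped the hypoxia peak at 13111 to 13160. The SYSY normoxia peak at 12931 to 13050 overlapped the hypoxia peak at 12991 to 13040, but its midpoint lay outside the window. The hypoxia peaks at 13781 to 13830 and 13921 to 13970 overlapped no SYSY normoxia peak. The stretch from 14001 to 15000 held 4 NEB peaks in hypoxia and 3 in normoxia, and 3 SYSY peaks in each condition. The longest peaks of the other lists lay at 16121 to 16290 in NEB hypoxia (170 bases), at 3501 to 3730 in NEB normoxia (230 bases) and at 14461 to 14690 in SYSY hypoxia (230 bases). The window from 13001 to 14000 was picked for its hypoxia counts, and no window count was tested. These counts therefore do not show a gain of positions in hypoxia.

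The second comparison was hypoxia against normoxia. Hypoxia had 11 more peaks than normoxia under NEB, a ratio of 1.73, and 11 more under SYSY, a ratio of 1.48. Neither difference exceeded counting error in a two-sided exact binomial test that treats peaks as independent (NEB p = 0.117, SYSY p = 0.185, and both 0.185 after Benjamini-Hochberg adjustment over the 2 tests). Covered bases did not follow the peak numbers in both labels. NEB peaks covered 340 bases more in hypoxia than in normoxia, and SYSY peaks covered 110 bases fewer. The mean peak length was 59.6 bases in NEB hypoxia against 80.7 in NEB normoxia, and 60.6 in SYSY hypoxia against 94.4 in SYSY normoxia. With 1 list in each condition, neither the difference in number nor the difference in length has a replicate check. When peaks at most 200 bases apart were joined, the excess of hypoxia peaks fell to 5 under NEB and 3 under SYSY. Without the longest peak of each list, SYSY peaks covered 50 bases more in hypoxia, so the direction for SYSY rested on those longest peaks.

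Much of what was found in normoxia was also found in hypoxia. Of the 15 NEB normoxia peaks, 12 overlapped a NEB hypoxia peak by at least 1 base. Of the 23 SYSY normoxia peaks, 19 overlapped a SYSY hypoxia peak. In the other direction, 12 of the 26 NEB hypoxia peaks and 21 of the 34 SYSY hypoxia peaks overlapped a normoxia peak of the same label. The NEB lists shared 630 bases, against a mean of 113 when 1 list was rotated around the circle. The SYSY lists shared 1350 bases, against a mean of 269.8. None of the other rotations shared as many bases in either label. The one-sided exact circular shift test gave p = 0.000604 for both, the smallest p that its 1657 positions allow, and 0.000805 after Benjamini-Hochberg adjustment over the 4 overlap tests.

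Peaks of both conditions under NEB included 3161 to 3210, near the end of MT-RNR2 on the standard map, and 15641 to 15690 in the cytochrome b gene MT-CYB. Under SYSY, both conditions had peaks at 1861 to 1910 in MT-RNR2, at 4711 to 4760 in the complex I gene MT-ND2, at 6221 to 6270 in the cytochrome c oxidase gene MT-CO1 and at 8441 to 8490 in MT-ATP8. The region at 13781 to 13840 was the only 1 of the 43 with peaks of both labels in hypoxia and of neither label in normoxia. No region had peaks of both labels in normoxia and of neither in hypoxia. In SYSY normoxia no peak lay between 14691 and the end of the numbering, nor before 481. Both NEB lists and the SYSY hypoxia list had peaks in 3 regions of that stretch, at 15461 to 15530, 15641 to 15690 and 16081 to 16290.

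The third comparison set the labels against each other within a condition. In hypoxia, 19 of the 26 NEB peaks overlapped a SYSY peak and 18 of the 34 SYSY peaks overlapped a NEB peak. The lists shared 890 bases, 4.62 times the mean over rotations of 193 bases, and no other rotation shared as many (exact circular shift test, p = 0.000604, adjusted p = 0.000805). In normoxia, 6 of the 15 NEB peaks and 6 of the 23 SYSY peaks overlapped the other label. The lists shared 360 bases, 2.27 times the mean of 158.5, and 60 of the 1657 rotations shared as many (exact circular shift test, p = 0.0362, adjusted p = 0.0362). In the same exact test on the 6 overlapping NEB peaks the call was lost (adjusted p = 0.110), as it was with peaks extended by 50 bases (adjusted p = 0.184) or 100 bases (adjusted p = 0.407) on each side. It was also lost when 1 peak was left out, for each of 10 peaks in these lists, with the highest exact p of 0.197 without the SYSY normoxia peak at 14281 to 14400. The difference in sharing between hypoxia and normoxia was not itself tested. The labels do not say which input libraries each list was called against, so part of the sharing within a condition can come from inputs used in common.

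**Figure D2:**
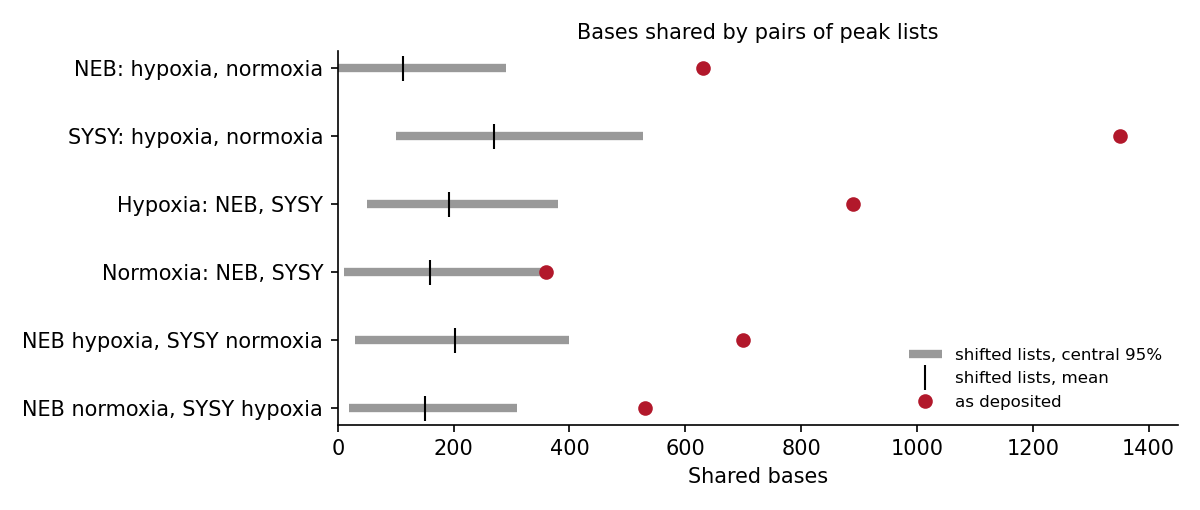
Bases shared by pairs of peak lists (horizontal axis, bases) as deposited (red points), with the mean (black tick) and the central 95% (grey bar) of the values after rotating 1 list around the circle. The deposited lists lie above the grey bar in every pair except NEB and SYSY in normoxia, where 360 shared bases lie at its upper end.

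Stretches without peaks were compared last, as a description of the lists, with a test added after the data were seen. The longest stretch without a peak was 4770 bases in NEB hypoxia, from 5511 to 10280, and 7510 bases in NEB normoxia, from 3731 to 11240. On the standard map the first of these stretches includes the genes of cytochrome c oxidase and of the ATP synthase subunits. Within the NEB hypoxia stretch, SYSY had 5 peaks in hypoxia and 6 in normoxia. When as many peaks as NEB had were drawn at random from both labels' peaks of a condition, a stretch as long as the NEB one was left in a share of 0.0801 of draws in hypoxia and 0.00272 in normoxia (permutation test, 100000 draws, 0.0801 and 0.00544 after Benjamini-Hochberg adjustment over the 2 tests). The draws treat single peaks as independent, so they cover neither neighbouring peaks that come or go together nor variation between libraries. The longest stretch without a SYSY peak was 1940 bases in hypoxia, from 6501 to 8440. In normoxia it was 2360 bases, from 14691 across the origin of the numbering to 480. Regions with peaks in both SYSY lists and neither NEB list numbered 7, and 1 region had peaks in both NEB lists and neither SYSY list. The SYSY lists held more peaks (34 in hypoxia and 23 in normoxia) than the NEB lists (26 and 15). List size alone can tilt these region numbers, which were not tested.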

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

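All tests in this part were chosen after the values were seen. Covered bases moved in opposite directions between the labels: hypoxia minus normoxia was 340 bases under NEB and -110 bases under SYSY. The difference between the labels was not tested, since each rests on 1 list in each condition. Without the longest peak of each list the SYSY value became 50 bases, so the opposite signs rested on those peaks, among them the 390 bases from 13351 to 13740 in SYSY normoxia.

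Hypoxia lists held more but shorter peaks than normoxia lists under both labels. A technical explanation is that wide normoxia peaks were called as several hypoxia peaks in the same place. Joining peaks at most 200 bases apart cut the excess of hypoxia peaks from 11 to 5 under NEB (14 against 9, exact binomial test, p = 0.405). Under SYSY the excess fell to 3 (16 against 13, exact binomial test, p = 0.711). Joining also merges hypoxia peaks far from any normoxia peak, as at 4711 to 4760 and 4941 to 4990 under NEB. The fall therefore does not measure splitting. Under NEB, 11 hypoxia peaks had no normoxia peak within 200 bases, against 1 normoxia peak with no hypoxia peak that near (exact binomial test, p = 0.00635), but these 11 stand in 6 places once neighbours at most 200 bases apart are counted together (6 against 1, p = 0.125). Under SYSY, 7 hypoxia peaks against 2 normoxia peaks (p = 0.180) stand in 5 places against 2 (exact binomial test, p = 0.453). Under NEB, 12 hypoxia and 12 normoxia peaks overlapped the other condition by at least 1 base, and 14 against 3 did not. Under SYSY these numbers were 21 and 19, and 13 against 4. In these lists the excess thus lay mainly in peaks overlapping none of the other condition. That count covers only pieces of a split peak that still overlap the other condition's peak. Pieces lying beside it are not covered, and the places at the 200-base limit are too few to decide. With so few places, a gain of positions was not shown in either label. Splitting of wide peaks is not excluded. Unequal depth or enrichment between the libraries and a response to oxygen stay open, untested.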

How the results depend on the processing

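Settings were fixed before the data were examined, except rotation in steps of 1 base, leaving out 1 peak at a time, joining neighbouring peaks, and leaving out the longest peaks for covered bases, which were added after the data were seen. No paired analysis was possible because the gene table's columns carry no library name or replicate number and each peak list stands alone for its group. For the same reason no replicate could be left out, the alternatives for gene expression were not run, and a stricter peak threshold was not run for want of a score. Sharing exceeded the adjusted threshold in 24 of 28 alternatives, 7 for each pair of lists, the rotation and single-peak settings among them. For NEB in both conditions, SYSY in both conditions and both labels in hypoxia, all 7 passed, with ratios of observed to mean sharing of 2.32 to 6.00, 1.83 to 5.04 and 1.73 to 4.87. For both labels in normoxia the ratio ranged from 1.06 to 3.42 (exact circular shift test, adjusted p 0.00121 to 0.407). There the call was lost when peaks overlapping by at least 1 base were counted (ratio 1.81), when peaks were extended by 50 bases (1.36) or 100 bases (1.06), and, in an added setting, without the peak whose absence gave the highest p (1.60). In other added settings, joining peaks at most 200 bases apart reduced the excess of hypoxia peaks from 11 to 5 under NEB and to 3 under SYSY, whereas joining at 100 bases left it at 11 in both. Leaving out the longest peaks, also added, reversed the SYSY difference in covered bases from -110 to 50. Unknown depth limits every number of peaks.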

Other observations

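The draws from both labels' peaks were planned before their own result was seen, but after the stretches without peaks had been seen. The other tests here were chosen after the values were seen. Positions recurred even between lists that differ in both label and condition. NEB hypoxia and SYSY normoxia shared 700 bases against a mean of 203 over rotations, and NEB normoxia and SYSY hypoxia shared 530 against 150.4. For both pairs no other rotation shared as many (exact circular shift test, p = 0.000604, the smallest it can give). This would count against inputs used in common within a condition only if the hypoxia and normoxia inputs differed in coverage. The input behind each list is not given and no input coverage was examined, so that explanation stays open. Methylated positions, and sequence or coverage features of mitochondrial DNA that favour a peak in any library, stay open too, because lists without heights or sequences do not separate them.

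A hypothesis that positions gained in hypoxia recur in both labels was tested on the bases covered in hypoxia and not in normoxia. These bases include edges of peaks found in both conditions, so not all are gained positions. An example is the NEB hypoxia peak at 451 to 500, which overlapped the NEB normoxia peak at 481 to 530 in part. The NEB list had 920 such bases and the SYSY list 710, and they shared 70, against a mean of 39.4 over rotations (exact circular shift test, p = 0.190, with 314 of 1657 rotations sharing as many). The test neither shows recurrence nor excludes it. For bases covered only in normoxia, 580 under NEB and 820 under SYSY, none were shared, against a mean of 28.7.

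The empty part of the NEB lists may not be an accident of placement. Stretches as long as the 4770 bases of NEB hypoxia arose in a share of 0.00182 of 100000 random placements of the same peaks, and those as long as the 7510 bases of NEB normoxia in a share of 0.00133. After Benjamini-Hochberg adjustment over the 4 lists both were 0.00364. Random placement does not keep the clustering of the real peaks, so clustering anywhere on the circle can also give such small shares. The longest stretches of SYSY hypoxia (0.285) and SYSY normoxia (0.413) were of a length that random placement often gives, which includes the stretch past 14691 without SYSY normoxia peaks. When as many peaks as NEB had were drawn at random from both labels' peaks, a stretch as long was left in a share of 0.00272 of draws for normoxia (adjusted 0.00544 over the 2 conditions) and 0.0801 for hypoxia. These draws also treat single peaks as independent, so neighbouring peaks that come or go together can give small shares. A difference between NEB and SYSY from 3731 to 11240 is thus only a hypothesis for normoxia. Over the shorter NEB stretch in hypoxia no difference was detectable. NEB hypoxia itself had peaks between 3731 and 11240, at 3871 to 3920, 4711 to 4760, 4941 to 4990, 5461 to 5510 and 10281 to 10330. With 1 NEB library in each condition, a trait of that library and of the label cannot be separated.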
